A study of Mus musculus with 27 samples.

How the data were processed

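RNA sequencing of mouse lung was analysed in 27 libraries of 9 groups, 3 per group. Total RNA was extracted with RNeasy kits and made into standard Illumina libraries, per the labels' protocols. The authors deposited log2 values of CPM (read counts scaled to the library total) plus a small offset, rounded to 1 decimal, with genes without reads listed at -10, as the values show. STAR, Partek and the mm39 build are named per the submitters' processing notes, which give no versions or settings. Taken back from the log scale with an offset of 0.001, the columns summed to between 936518 and 961831 CPM, a ratio of 1.03. The smallest steps above the floor put the depth at about 15.2 to 23.2 M reads per library (rounding error 3.53%), and 3 reads at 0.130 to 0.198 CPM, which covers counting error only. Of the gene identifiers 17034 (99.8%) matched GENCODE M21 (GRCm38), another build than mm39, which was used only for chromosome names, transcript length and GC content.

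Values were tested as log2(CPM + 1) without further scaling, so fold changes are on that scale and understate the change of low genes. Genes with at least 1 CPM in at least 3 libraries were kept, 14636 of 17062. All 27 libraries entered a single model with group means, fitted with limma 3.58.1 (eBayes with trend and robust, statmod 1.5.0) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, 2-sided. Sample labels do not say that replicates are separate animals, so p-values measure the spread between samples. The comparisons, tests, gene lists and alternatives were set before the data were examined, for a count table or for normalized values, and the part for normalized values was used. The 12 comparisons were made within title sets, except ACE2 against the mean of both male vehicle groups and the vehicle groups against each other. In the text, levels are mean ± SD in CPM, and log2 changes in parentheses are limma estimates.

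Genes were named by a fixed rule. They are (a) Mas1, Ace2, Ace, Agt and Agtr1a everywhere; (b) the 5 largest called rises and falls without overlap of the groups and with a mean of at least 2 CPM, predicted genes and receptor segments left out; (c) up to 4 called members with the smallest p of each list called by camera or with at least 3 called members; (d) the 3 genes with the smallest p where fewer than 5 were called; (e) Ddx3y to check sex. Genes named outside it are marked as chosen after their values were seen. Of 48 gene lists for pathways, cell types and tissues, 46 had at least 4 measured members, and those of thymus and oesophagus had too few and were not tested. Lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over lists within a comparison, and again with an estimated correlation and with fry, which asks whether genes of a list move one way on balance and does not compare them with other genes. Similarities of fold changes across genes were tested by exact permutation of the labels within each comparison, 2-sided, and adjusted over 5.

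The fit was tested on simulated data for 14636 genes with 200 changed. For vehicle against normoxic it recovered 88 of 100 genes changed by a log2 of 1 and 95 of 100 changed by 2, with 5.18% false among 193 calls. For Alt00/Lisi over both sexes it recovered 95 and 99 with 2.02% false among 198, and for ACE2 in wild-type males 94 and 99 with 3.02% false among 199. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.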

Results

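RNA was sequenced from 27 mouse lung libraries in 9 groups of 3. The model of pulmonary hypertension was 10% oxygen for 3 weeks with weekly Sugen, an inhibitor of the vascular endothelial growth factor receptor. Animals received vehicle, ACE2 (the carboxypeptidase whose peptide product acts on the receptor Mas), AR234960 (a small agonist of Mas) or Alt00 with lisinopril, which blocks angiotensin-converting enzyme, while a normoxic group stayed outside the model. Sample titles start with AR, AUS or ACE, and treatments are nested in these sets. The AR set held normoxic, vehicle and AR234960 wild-type males, the AUS set held vehicle and Alt00/Lisi wild-type animals of both sexes, and the ACE set held ACE2-treated males labelled WT or Mas KO without a vehicle group. At about 15.2 to 23.2 M reads per library, 3 reads correspond to 0.130 to 0.198 CPM. Of 17062 genes in the deposited table, 14636 were tested.

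Mas1, the gene deleted in the knockout, ran against the genotype label. It lay at 1.07 to 1.87 CPM in the 3 libraries labelled Mas KO and at 0 to 0.378 CPM in the other 24 libraries, a few reads at most. Between the ACE2-treated groups it was called higher in those labelled Mas KO (1.39 ± 0.42 against 0.16 ± 0.139 CPM, n = 3 each, limma adjusted p = 0.00698), a call lost without the first replicate of either group. A value for a whole gene cannot show whether the reads lie inside the deleted part, so these libraries are called the libraries labelled Mas KO throughout. The sex labels fitted the Y-linked Ddx3y, which had 0 reads in all 6 female libraries and 73.5 to 111 CPM in the 21 male libraries. Xist and Ren1 were not in the table.

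**Figure D1:**
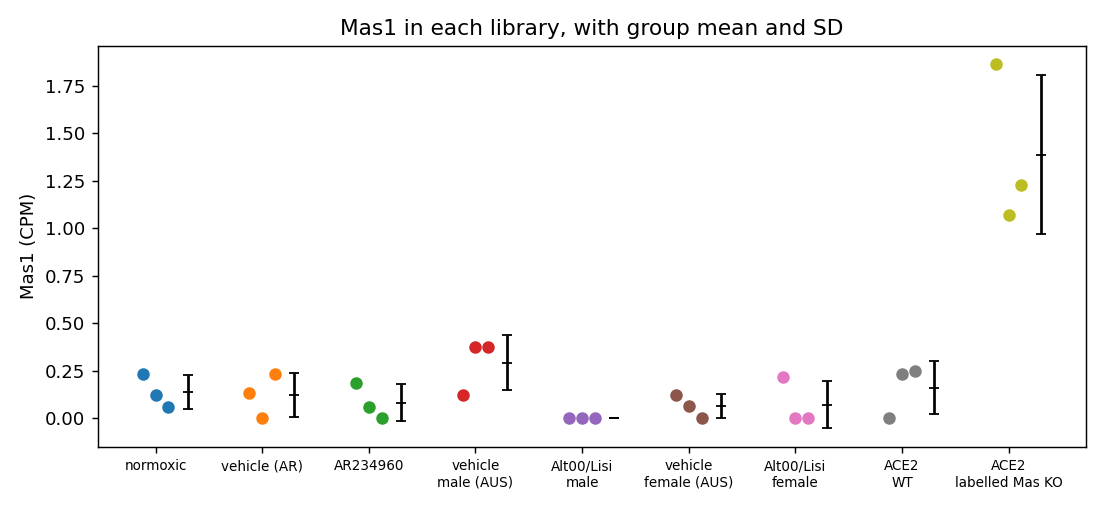
Mas1 in CPM (vertical axis) in each library, by group, with the mean and SD of each group as a bar beside the 3 points.

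The first principal component held 22.9% of the variance and separated the title sets: the 9 AR libraries lay at -14.1 or lower and the other 18 at 1.21 or higher. The second held 11.4% and set libraries of the same group apart, among them AR vehicle replicate 3 and Alt00/Lisi female replicate 2. Pearson correlations within groups, across genes, ran from 0.966 to 0.993. Haemoglobin transcripts took 0.0622% to 2.43% of the CPM, with the highest share in Alt00/Lisi female replicate 2.

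**Figure D2:**
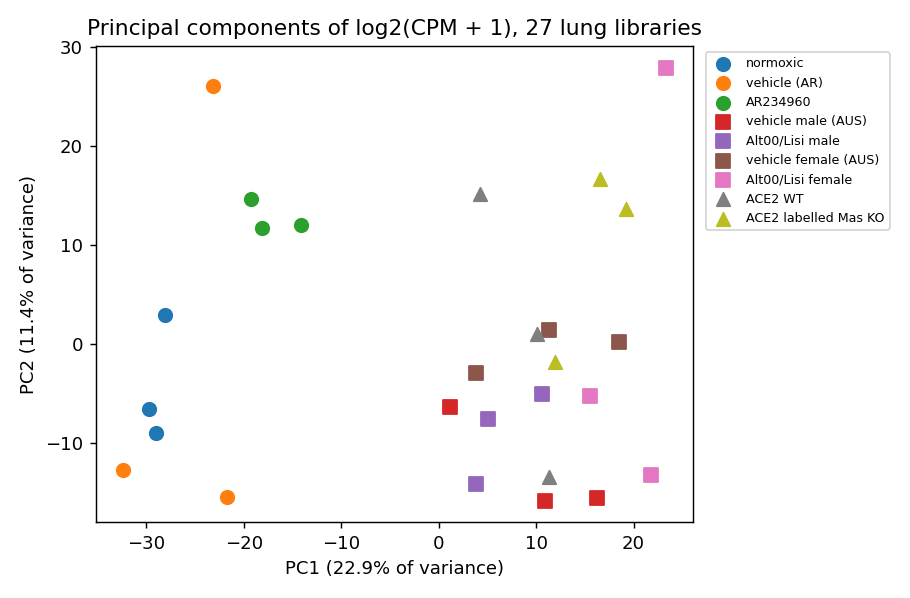
First and second principal components of log2(CPM + 1) for the 27 libraries, with colours for groups and symbols for title sets (circles AR, squares AUS, triangles ACE).

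The effect of hypoxia with Sugen was read from AR vehicle males against normoxic males. Genes of lymphatic endothelium rose: Reln, a glycoprotein secreted by lymphatic vessels, went to 25.5 ± 2.65 against 8.27 ± 1.46 CPM (n = 3 each, log2 change 1.52 ± 0.19 SE, limma adjusted p = 0.000207) and Mmrn1, an extracellular protein of the same cells, to 42.2 ± 0 against 16.9 ± 2.89 CPM (adjusted p = 0.000844, limma). The lymphatic chemokine Ccl21a (103 ± 22.4 against 49.7 ± 3.89 CPM), which has near-identical copies and is therefore uncertain, and the neurotrophin receptor Ntrk2 (63.8 ± 23.7 against 23.9 ± 4.09 CPM) rose too. Esm1, a proteoglycan secreted by endothelium, fell to 9.15 ± 2.17 against 34.1 ± 15.5 CPM (limma adjusted p = 0.00745).

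In this comparison 20 genes passed (234 with array weights), 14 higher and 6 lower in vehicle, and 1128 had an unadjusted p under 0.05. Further rises by log2 change were Adam15 (0.89), Cpt1a (0.86) and Igfbp2 (0.80), the last of them a marker of alveolar type 1 cells and Cpt1a the enzyme that admits fatty acids to mitochondria. Further falls were Olfm2 (-1.60), Treml2 (-1.02), Tmem132c (-0.70) and Dpt (-0.46). Of the 10 lymphatic endothelial markers, 3 rose over all genes and 4 adjusted over the list alone, and limma camera called the list higher (median 0.41, 0.18 without AR vehicle replicate 3, adjusted p = 1.57e-05), as it did with an estimated correlation (adjusted p = 0.0218). All 24 genes of fatty acid oxidation and PPAR targets lay higher, with Cpt1a alone passing (median 0.19, 0.0659 without AR vehicle replicate 2 and 0.33 without replicate 3, camera adjusted p = 4.23e-05 and 0.218 with an estimated correlation). Lymphocyte and platelet markers lay lower: all 12 B cell markers (median log2 change -0.94), all 13 natural killer cell markers (-0.54) and all 12 platelet and megakaryocyte markers (-0.57). Of these, 12, 5 and 1 fell, but only adjusted over the list alone. Camera called the 3 lists lower (limma adjusted p = 5.51e-17, 2.58e-10 and 7.84e-10), and each had adjusted p = 0.0682 with an estimated correlation. The sterol and lipid synthesis genes (median -0.23, -0.13 without that replicate, 19 of 21 lower, camera adjusted p = 2.58e-08 and 0.108 with an estimated correlation) and the T cell markers (-0.42, 1 fall adjusted over the list alone, 2.58e-08 and 0.108) lay lower in the same way.

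In the model 13 further lists were called by limma camera (median log2 change, adjusted p, members called adjusted over the list alone) and lost with an estimated correlation (adjusted p = 0.152 to 0.85). Higher were the interferon-stimulated genes (0.27, 0.00179), extracellular matrix genes (0.10, 0.0289, 3 rose), pericyte genes (0.18, 0.0301) and endothelial identity genes (0.15, 0.037, 1 rose). Lower were the mesothelial markers (-0.54, 3.87e-07, 3 fell), alveolar type 2 markers (-0.18, 4.23e-05, 1 fell), unfolded protein response genes (-0.16, 0.000231) and oxidative phosphorylation genes (-0.08, 0.00422). Immediate early genes (-0.33, 0.00631), alveolar type 1 markers (-0.13, 0.0128, 1 rose by either count) and heat shock genes (-0.32, 0.0238) lay lower too. Cardiac muscle genes (-0.58, 0.0319) and skeletal muscle genes (-0.45, 0.0471) lay lower too. The count of 20 fell to 2, 10 and 8 without normoxic replicates 1, 2 and 3 and to 6 and 12 without AR vehicle replicates 1 and 2, and 2 of the 12 named genes called and 10 of 20 lists called by camera passed in every fit with 1 library left out, Reln and Mmrn1 being those genes. Camera calls were lost (medians given) without normoxic replicates 1 (pericyte 0.13, endothelial 0.10), 2 (cardiac muscle -0.35, skeletal muscle -0.53) and 3 (matrix 0.08, heat shock -0.13, immediate early -0.30, cardiac muscle -0.57, skeletal muscle -0.25). Others were lost without AR vehicle replicates 1 (heat shock -0.15, alveolar type 1 -0.09), 2 (pericyte 0.17, alveolar type 1 -0.14) and 3 (matrix 0.13, endothelial 0.02, interferon 0.15, oxidative phosphorylation 0.04, cardiac muscle 0.85, skeletal muscle 0.21).

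AR234960 was used to test Mas activation in the same set, against the AR vehicle males. Eln, the elastin precursor, rose to 659 ± 159 against 234 ± 24.4 CPM (n = 3 each, log2 change 1.46 ± 0.27 SE, limma adjusted p = 0.0155) and the vessel-wall collagen Col15a1 to 43.9 ± 15 against 20.1 ± 5.11 CPM (limma adjusted p = 0.0319). The neutrophil granule genes Ngp (19 ± 9.05 against 1.09 ± 0.804 CPM) and Camp (3.73 ± 1.5 against 0.138 ± 0.0854 CPM) rose from low levels. Hs3st1, a heparan sulfate sulfotransferase, fell to 16.7 ± 3.89 against 43.2 ± 1.75 CPM (limma adjusted p = 0.000842), as did the little studied Ankrd63 (1.49 ± 1.17 against 9.91 ± 1.37 CPM).

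Of 30 genes that passed, 15 were higher and 15 lower under AR234960, and 1237 had an unadjusted p under 0.05. Other rises by log2 change were Col5a3 (1.65), Adamts4 (1.57) and Col6a2 (0.63), where Col5a3 stood at 31 ± 28.6 against 6.97 ± 0.483 CPM and so varied widely between treated libraries. Other falls were Lrtm2 (-1.57), Samd5 (-1.15) and Wnt7a (-0.999). Of the 39 extracellular matrix genes, 3 rose over all genes, while 19 rose and 1 fell adjusted over the list alone (median 0.47, limma camera adjusted p = 1.6e-19 and 0.121 with an estimated correlation). The glucocorticoid-responsive genes, targets of the stress hormone receptor such as Fkbp5, lay higher in 13 of 14, with 6 passing only adjusted over the list alone (median 0.75, 0.50 without AR vehicle replicate 3, camera adjusted p = 6.52e-13 and 0.121 with an estimated correlation). Of 14 neutrophil markers, Ngp and Camp rose by either count (median 0.51, limma camera adjusted p = 1.79e-06 and 0.337 with an estimated correlation). Sterol and lipid synthesis genes lay lower, with 8 of 21 falling only adjusted over the list alone (median -0.29, 1.79e-06 and 0.184). Without AR234960 replicate 1 the median of the matrix genes was 0.30 and that of the neutrophil markers 0.18, and without AR vehicle replicate 1 that of the sterol genes was -0.16, each still called.

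Camera called 13 further lists under AR234960 (limma; as for the model), none with an estimated correlation (adjusted p = 0.121 to 0.586). Higher were the cell cycle genes (0.40, 2e-12), mesothelial markers (0.72, 3.65e-08, 5 rose), platelet and megakaryocyte markers (0.44, 6.43e-08, 3 rose) and erythroid and haemoglobin genes (1.26, 6.6e-05, 2 rose). Monocyte and interstitial macrophage markers (0.12, 0.000275), hypoxia-inducible factor targets (0.16, 0.000763), mast cell and basophil markers (0.20, 0.00773, 2 rose) and alveolar type 2 markers (0.12, 0.0317, 1 rose) lay higher too. Unfolded protein response genes (0.12, 0.0329) and alveolar macrophage markers (0.19, 0.0329) lay higher too. Lower were the vascular smooth muscle contractile genes (-0.27, 6.18e-05, 3 fell), B cell markers (-0.51, 0.00143) and vasoactive mediators and receptors (-0.19, 0.0272, 3 fell). The count of 30 became 5, 8 and 91 without AR234960 replicates 1, 2 and 3, and 7 and 64 without AR vehicle replicates 1 and 3. With each library left out in turn 3 of the 12 named genes called and 8 of 17 lists called by camera passed, the genes being Ankrd63, Hs3st1 and Camp. Camera calls were lost (medians given) without AR234960 replicates 1 (hypoxia 0.03, monocyte 0.01) and 3 (unfolded protein 0.03, alveolar type 2 0.07, alveolar macrophage 0.06, erythroid 0.60). Others were lost without AR vehicle replicates 1 (contractile -0.11, unfolded protein 0.07, alveolar type 2 0.10, alveolar macrophage 0.11, B cell -0.28), 2 (alveolar type 2 0.12, B cell -0.33) and 3 (vasoactive -0.15). Without AR vehicle replicate 3 the contractile median was -0.58. With array weights 369 genes passed, and with the 6 libraries of the comparison alone 0 by limma, 1477 at an unadjusted p under 0.05.

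**Figure D3:**
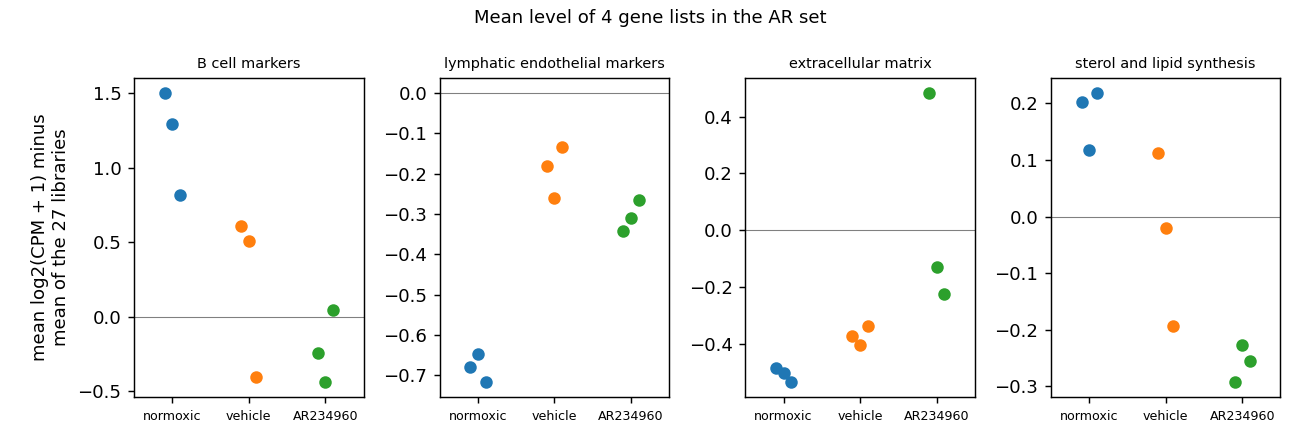
Mean log2(CPM + 1) of 4 gene lists in each library of the AR set, less the mean of the 27 libraries (vertical axes differ between panels). Points are libraries, 3 per group, and in the B cell and sterol panels all AR vehicle libraries lie below the normoxic ones, with replicate 3 lowest.

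AR234960-treated lungs were also set against normoxic lungs, to see how far they stood from the normoxic state. Lymphocyte genes fell: Pax5, the transcription factor of the B lineage, went to 11.7 ± 1.95 against 46 ± 15.1 CPM (n = 3 each, log2 change -1.85 ± 0.33 SE, limma adjusted p = 0.00425) and Fcer2a, a B cell surface receptor, to 6.21 ± 0.251 against 25.8 ± 5.38 CPM (limma adjusted p = 0.0016). Eln rose to 659 ± 159 against 174 ± 29.1 CPM (limma adjusted p = 0.000736) and Ntrk2 to 114 ± 4.62 against 23.9 ± 4.09 CPM (limma adjusted p = 0.0001). Ldlr, the receptor that takes up cholesterol, fell to 67.3 ± 7 against 109 ± 4.31 CPM (limma adjusted p = 0.00295), and Plvap, which forms the diaphragms of capillary windows, to 306 ± 71.5 against 677 ± 46.9 CPM. The glucocorticoid target Fkbp5 rose to 151 ± 111 against 24.3 ± 6.18 CPM, a wide spread.

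In total 286 genes passed (1764 with array weights, 693 with the libraries of the comparison alone), 125 higher and 161 lower. By log2 change the remaining large shifts were Ngp (3.23) and Tcf23 (1.86) upward and Ankrd63 (-3.28), Esm1 (-2.14) and Tnfrsf13c (-1.79) downward. Of 19 lists called by camera, 6 kept the call with an estimated correlation. Of these, 39 extracellular matrix genes held 13 rises over all genes, led by Eln (1.89), Mmp2 (0.89), Col15a1 (1.25) and Bgn (0.60), and 26 rises with 1 fall adjusted over the list alone (median 0.57, limma adjusted p = 2.45e-24 and 0.0207 with an estimated correlation). Of 12 B cell markers, 10 fell over all genes, among them Cr2 (-1.64), Pax5 (-1.85), Ebf1 (-0.77) and Blk (-1.28), and 12 adjusted over the list alone (median -1.44, limma adjusted p = 2.92e-22 and 0.0207). Of 21 sterol and lipid synthesis genes, 8 fell, led by Cyp51 (-0.65), Sc5d (-0.59), Ldlr (-0.69) and Idi1 (-0.75), and 17 adjusted over the list alone (median -0.47, limma 6.65e-19 and 0.0207). Of 15 T cell markers, 4 fell (Cd8a (-1.13), Ccr7 (-1.03), Lck (-0.96) and Bcl11b (-0.71)) and 10 adjusted over the list alone (median -0.65, limma 7.55e-11 and 0.0453). Of 13 natural killer cell markers, 3 fell (Klrk1 (-1.09), Gzma (-1.07) and Prf1 (-0.94)) and 10 adjusted over the list alone (median -0.74, limma 1.28e-10 and 0.0469). Of 10 lymphatic endothelial markers, 3 rose (Reln (1.20), Mmrn1 (1.09) and Ccl21a (0.85)), and 3 rose and 1 fell adjusted over the list alone (median 0.26, limma 0.000187 and 0.0207).

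Called members of other lists between AR234960 and normoxia included the glucocorticoid targets Sgk1 (0.93), Cdkn1a (1.65), Fkbp5 (2.35) and Map3k6 (1.41), with 5 of 14 rising adjusted over the list alone (median 0.76, limma camera 7.08e-09 and 0.138 with an estimated correlation). Cpt1a, Plin2 and Angptl4 rose among fatty acid oxidation and PPAR targets (log2 0.89, 0.46 and 1.66, 5 adjusted over the list alone, list 4.12e-05 and 0.217). The oxygen-responsive Ndrg1 (0.69) and Ddit4 (0.89) rose, with 3 rising and 1 falling adjusted over the list alone (list 0.0368 and 0.481). The capillary genes Ednrb (-0.89), Plvap (-1.16) and Fibin (-0.78) fell, although their list missed the camera threshold (adjusted p = 0.055, limma) with 3 rises and 5 falls adjusted over the list alone. Bmp6 (-0.86) and Tgfb2 (-0.46) fell and Fst (1.03) rose. In alveolar type 1 markers Igfbp2 rose (0.73) and Akap5 (-0.73) and Emp2 (-0.50) fell (1 rise and 5 falls adjusted over the list alone, limma 0.00281 and 0.4). Macrophage genes C1qc (0.74), C1qb (0.84) and Atp6v0d2 (0.83) and the neutrophil gene Camp (1.86) rose.

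The lists still to give for AR234960 against normoxia lost their camera call with an estimated correlation at adjusted p = 0.332 to 0.756 (limma; as for the model). Higher were the cell cycle genes (0.38, 9.08e-07), monocyte and interstitial macrophage markers (0.44, 6.13e-05, 5 rose, 2 over all genes) and neutrophil markers (0.71, 0.000106, 2 rose by either count). Erythroid and haemoglobin genes (1.00, 0.00781, 1 rose) and alveolar macrophage markers (0.19, 0.047, 1 rose by either count) lay higher too. Lower were the immediate early genes (-0.46, 0.000986), cardiac muscle genes (-0.80, 0.00371), vascular smooth muscle contractile genes (-0.20, 0.0368) and oxidative phosphorylation genes (-0.08, 0.0467). The count of 286 fell to 104 and 70 without AR234960 replicates 1 and 2, and to 60, 102 and 166 without normoxic replicates 1, 2 and 3. Through all fits with 1 library left out 20 of the 51 named genes called and 13 of 19 lists called by camera passed, among them the 6 that held with an estimated correlation, and hypoxia, contractile, oxidative phosphorylation, alveolar macrophage, erythroid and cardiac muscle were lost. Without AR234960 replicate 1 the monocyte median was 0.0874 and the neutrophil median 0.24.

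Whether AR234960 moved the lungs back along the axis of the model was asked by correlating fold changes across 14636 genes, which are not independent replicates. The change under AR234960 and that of the model had Pearson r = -0.281 and Spearman rho = -0.361 (exact permutation p = 0.56 over 400 labelings, adjusted p = 0.75 over 5 similarities). Both share the 3 vehicle libraries, and simulated unchanged groups against them gave a mean r of -0.485 (95% between -0.764 and -0.110). The covariance was -0.0166 against -0.0227 simulated, a difference of 0.00612. Kalrn, an exchange factor of the cytoskeleton, and the laminin chain Lamc3 rose in vehicle and fell under AR234960, where independent lists would share 0.0143 genes (0.00615 for the opposite pattern, which no gene showed). In 100 draws of unchanged groups 0.06 genes were called on average, too few to measure what such groups share. Kalrn and Lamc3 were chosen after their values were seen. Of the 20 genes of the model 15 had the opposite sign under AR234960. The 20 of smallest p in those draws gave 18.13 on average (95% between 12.475 and 20) but were rarely called, so they set no baseline. The vehicle group could not be split into sides of 2 libraries, so part of this overlap can come from the shared libraries.

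Alt00 with lisinopril was compared with vehicle within the AUS set, in males, in females and over both. In males the genes with the smallest p were F13a1, a transglutaminase of macrophages and platelets (18.1 ± 2.75 against 64.7 ± 28 CPM, n = 3 each, log2 change -1.71 ± 0.32 SE), the macrophage Fc receptor Fcgr1 (2.13 ± 1.06 against 7.11 ± 3.18 CPM) and Hspa5, the chaperone of the endoplasmic reticulum (642 ± 228 against 1050 ± 82 CPM), each with a limma adjusted p of 0.223. They lay lower under treatment in every library than in any vehicle library without passing. In females the smallest p values belonged to Proser3 (-0.87), Tmem163 (-0.75) and Zfp668 (-0.54), none past the threshold (limma adjusted p = 0.538). Over both sexes they belonged to Klhl29 (-0.73), Zfp668 (-0.41) and Proser3 (-0.61).

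By limma 0 genes passed in males (1143 at an unadjusted p under 0.05), 0 in females (1088) and 0 over both sexes (1140), and the difference between the sexes gave 0 (1033), led by Fam83b (-1.69), Arhgef37 (2.12) and Agbl5 (-0.90) at adjusted p values from 0.429. Groups did not overlap for 6.50% of genes in males and 5.27% in females, where chance gives 10%. Recovery of 95 of 100 simulated genes changed by a log2 of 1 (both sexes) need not hold here, since counts depended on single libraries. Without Alt00/Lisi male replicate 3, 21 genes passed in males and 10 over both sexes. Without Alt00/Lisi female replicate 1, 25 passed in females and 1 over both. Of the 19 genes of the unfolded protein response in males, 18 lay lower and 12 fell only adjusted over the list alone (median -0.33, limma camera adjusted p = 2.56e-14 and 0.118 with an estimated correlation, fry adjusted p = 0.0248). Over both sexes 10 fell adjusted over the list alone (median -0.22, 6.35e-10 and 0.42). The B cell markers lay higher in males in 12 of 12 (median 0.56, 1 rise adjusted over the list alone, limma 1.36e-06, adjusted p = 0.575 with an estimated correlation).

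Further camera calls for Alt00/Lisi were lost with an estimated correlation (limma; as for the model), those in males first. Higher were the immediate early genes (0.47, 7.09e-06, 1 rose), T cell markers (0.28, 0.00357, 2 rose) and ciliated cell markers (0.23, 0.0129). Natural killer cell markers (0.26, 0.0172) and C57BL/6 substrain genes (0.16, 0.0172) lay higher too. Lower were the monocyte and interstitial macrophage markers (-0.28, 1.36e-06, 3 fell), interferon-stimulated genes (-0.21, 6.55e-05, 1 fell), neutrophil markers (-0.59, 0.000104, 1 fell) and sterol and lipid synthesis genes (-0.13, 0.00124). Plasma cell markers (-0.26, 0.0172, 2 fell), heat shock genes (-0.40, 0.0195) and alveolar macrophage markers (-0.19, 0.0319) lay lower too. With an estimated correlation their adjusted p was 0.357 to 0.703. Over both sexes 9 further lists were called. Higher were the B cell markers (0.24, 0.00403) and immediate early genes (0.14, 0.00927). Lower were the interferon-stimulated genes (-0.23, 1.33e-05, 2 fell), monocyte and interstitial macrophage markers (-0.14, 0.00403, 2 fell), sterol and lipid synthesis genes (-0.11, 0.00403) and heat shock genes (-0.37, 0.00403). Neutrophil markers (-0.46, 0.00437), circadian clock genes (-0.22, 0.00626, 7 fell) and extracellular matrix genes (-0.12, 0.0332) lay lower too. Their adjusted p with an estimated correlation was 0.623 to 0.869. In females the erythroid and haemoglobin genes were called alone (median 1.03, 0.0171 and 0.989), and without Alt00/Lisi female replicate 2, the library with most haemoglobin, the median was -0.13. Throughout the fits with 1 library left out, 5 of 14 lists called by camera in males passed (unfolded protein response, B cell, T cell, monocyte and interferon) and 2 of 10 lists called by camera over both sexes (unfolded protein response and interferon). In males the direction of the heat shock genes in camera turned without Alt00/Lisi replicate 1 (median -0.16), and the immediate early genes were lost without replicate 2 (0.12, 0.0085 over both sexes) and weaker without vehicle replicate 3 (0.18).

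Vehicle-treated females and males of the AUS set were compared for sex differences in the model. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in females and 89.2, 45.3, 27.5 and 20.3 CPM on average in males. Kdm6a, an X-linked demethylase that escapes inactivation, was higher in females (64.3 ± 7.97 against 37.2 ± 7.08 CPM, n = 3 each, log2 change 0.78 ± 0.14 SE, limma adjusted p = 0.0259). Arhgef37, an autosomal exchange factor, was lower (0.945 ± 0.327 against 6.53 ± 0.809 CPM, limma adjusted p = 0.00433). With 1 gene higher and 6 lower, 7 passed, and 4 passed without vehicle female replicate 2.

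Of the sex-linked list, 4 of 4 measured genes fell by either count, over all genes or adjusted over the list alone, and camera kept the call with an estimated correlation (limma adjusted p = 6.4e-08). In the comparison of the sexes 16 other lists were called by camera and lost with an estimated correlation at adjusted p = 0.0662 to 0.735 (limma; as for the model, females relative to males). Higher were the cell cycle genes (0.42, 4.22e-08), natural killer cell markers (0.49, 5.51e-07, 2 rose) and T cell markers (0.36, 6.37e-07, 5 rose). B cell markers (0.32, 0.00125) and mast cell and basophil markers (0.17, 0.0169) lay higher too. Lower were the monocyte and interstitial macrophage markers (-0.23, 6.37e-07, 3 fell), cardiac muscle genes (-0.998, 6.75e-06), fatty acid oxidation and PPAR targets (-0.16, 0.000555) and lymphatic endothelial markers (-0.42, 0.00077). Club cell markers (-0.34, 0.000864, 1 fell), unfolded protein response genes (-0.13, 0.00125), skeletal muscle genes (-0.53, 0.00779) and circadian clock genes (-0.23, 0.00779) lay lower too. Adipocyte markers (-0.53, 0.00903), vascular smooth muscle contractile genes (-0.13, 0.035) and arterial and venous endothelial genes (-0.05, 0.0368, 3 fell) lay lower too. In every fit with 1 library left out 4 of the 6 named genes called and 10 of 17 lists called by camera passed, the others being contractile, unfolded protein response, circadian clock, mast cell, adipocyte, arterial and B cell.

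The ACE set held no vehicle, so ACE2-treated males labelled Mas KO against WT cannot show whether the ACE2 effect needs Mas. The detoxifying enzyme Glo1 rose in the libraries labelled Mas KO (125 ± 4.95 against 53.2 ± 2.15 CPM, n = 3 each, log2 change 1.22 ± 0.10 SE, limma adjusted p = 1.9e-08), and so did the glutamate receptor subunit Grik3 (4.88 ± 1.06 against 0.14 ± 0.123 CPM, limma adjusted p = 8.86e-09). Hdac1, a histone deacetylase, fell to 16 ± 1.11 against 42.3 ± 2.93 CPM (limma adjusted p = 8.86e-09), the centrosomal Cep85 to 15.1 ± 2.88 against 92.8 ± 25.5 CPM and the morphogen Wnt4 to 7.1 ± 1.68 against 20.2 ± 2.17 CPM. Ide, the insulin-degrading enzyme and a gene that differs between C57BL/6 substrains, fell to 58.4 ± 2.31 against 134 ± 5.3 CPM (limma adjusted p = 0.00199).

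Of 29 genes that passed (101 with array weights), 9 were higher and 20 lower in the libraries labelled Mas KO, and 1057 had an unadjusted p under 0.05. Of the called genes 11 lie on chromosome 17, which carries Mas1 and Glo1, and 8 on chromosome 4, which carries Grik3, Cep85, Wnt4 and Hdac1. Hmga1 on chromosome 17 fell (7.71 ± 1.28 against 24.3 ± 1.68 CPM) while its near-identical copy Hmga1b rose (23.2 ± 1.81 against 6.58 ± 2.01 CPM), so both are uncertain because counting can split their reads. Other changes were Grm4 (-1.70), Cd59a (0.95) and Ndn (0.81) on the log2 scale. Of 7 C57BL/6 substrain genes, Ide fell over all genes, while 1 rose and 3 fell adjusted over the list alone (median -0.18, limma camera 0.006 and 0.513 with an estimated correlation). Cardiac muscle genes, of atrial and pulmonary vein muscle or the heart, lay lower in 17 of 18 (median -1.46, -0.93 without ACE2 WT replicate 3, 1.11e-06 and 0.579). The other 10 lists called by camera were lost with an estimated correlation at adjusted p = 0.513 to 0.957 (limma; as for the model). Higher were the B cell markers (0.46, 0.000159) and hypoxia-inducible factor targets (0.17, 0.00308). Lower were the adipocyte markers (-1.22, 2.13e-05), interferon-stimulated genes (-0.22, 0.000186), heat shock genes (-0.36, 0.00308) and circadian clock genes (-0.29, 0.012). Unfolded protein response genes (-0.17, 0.0271), skeletal muscle genes (-0.43, 0.0279), immediate early genes (-0.27, 0.0321) and NF-kB inflammatory genes (-0.30, 0.0321) lay lower too. Camera calls were lost (medians given) without Mas KO label replicates 2 (NF-kB -0.25, unfolded protein -0.12, heat shock -0.30, immediate early -0.14, skeletal muscle -0.52) and 3 (NF-kB -0.10, immediate early -0.10). Others were lost without ACE2 WT replicates 2 (unfolded protein -0.15) and 3 (NF-kB -0.23, interferon -0.11, unfolded protein -0.13, heat shock -0.16, immediate early 0.11, circadian clock -0.13, skeletal muscle -0.29, adipocyte -0.33). Without ACE2 WT replicate 1 the medians were -0.0645 (substrain), 0.75 (B cell), -0.60 (heat shock) and -0.51 (immediate early), those of skeletal muscle -0.65 and -0.23 without Mas KO label replicates 1 and 3, and those of immediate early genes -0.61 and -0.46 without Mas KO label replicate 1 and ACE2 WT replicate 2, each still called. Whichever library was left out, 7 of the 12 named genes called and 4 of 12 lists called by camera passed, the genes being Grik3, Glo1, Cep85, Hmga1, Wnt4, Hdac1 and Ide.

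ACE2-treated wild-type males were set against the 6 male vehicle libraries of the AR and AUS sets, since the ACE set held no vehicle. Genes of alveolar type 2 cells, which make surfactant, fell: Sftpa1 went to 1358 ± 157 against 2250 ± 398 CPM (n = 3 against 6, log2 change -0.72 ± 0.11 SE, limma adjusted p = 0.000454), the phosphate transporter Slc34a2 to 1004 ± 104 against 1536 ± 80.6 CPM and the transcription factor Etv5 to 67.5 ± 10.0 against 131 ± 12.6 CPM. Of 14 capillary genes 4 fell and 1 rose (4 and 2 adjusted over the list alone, list not called by camera, adjusted p = 0.352), with falls in Aplnr, the apelin receptor (44.6 ± 6.78 against 95 ± 6.69 CPM, limma adjusted p = 0.003), and the carbonic anhydrase Car4 (56.1 ± 7.75 against 108 ± 19.6 CPM). Endothelial Emcn (98.1 ± 18.7 against 62.7 ± 21.5 CPM) and Cdh5 (1562 ± 216 against 1020 ± 228 CPM) rose, as did the vessel-wall collagen Col8a1 (55.8 ± 3.87 against 26.1 ± 4.9 CPM, limma adjusted p = 0.000512). Treatment and title set cannot be separated in this comparison, and the vehicle groups of the 2 sets differ from each other at 1991 genes.

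In all 365 genes passed (996 with array weights), 213 higher and 152 lower under ACE2, and 59 passed in the same direction against each vehicle group on its own. Counts were 224, 161 and 143 without ACE2 WT replicates 1, 2 and 3. Under rule (b) log2 rises were led by Cyp1b1 (5.20), Ntrk2 (1.92), Gdf15 (1.74), Cdk19 (1.66) and Olfr78 (1.61). Falls were led by Igfbp3 (-1.63), Ccr2 (-1.41), Nrxn1 (-1.39), Septin3 (-1.37) and Nptx1 (-1.37). Of 12 alveolar type 2 markers, 7 fell over all genes and 11 adjusted over the list alone (median -0.47, limma camera 1.22e-12 and 0.174 with an estimated correlation, fry 0.000776), Lamp3 (-0.52) among them. Ube2c (1.26) alone rose of 41 cell cycle genes, 20 adjusted over the list alone (median 0.63, 2.52e-11 and 0.485). Of 6 liver genes, secreted protein genes such as Serpina1b (5.29 ± 3.77 against 0.0682 ± 0.111 CPM, log2 2.28, uncertain for near-identical copies), 1 rose over all genes and 5 adjusted over the list alone (median 1.47, 7.31e-05 and 0.415).

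Other called members that rose under ACE2 in wild-type males included, by log2 change, the endothelial gene Sox17 (0.65). Matrix genes among them were Loxl2 (0.72), Tnc (0.998) and Col15a1 (0.77). Cald1 (0.40) and Sncg (0.81) of the contractile list rose too. So did the glycolytic Aldoa (0.47), Ndrg1 (0.51), Cdkn1a (1.32) and Ide (0.76). Falls were seen in Fibin (-0.81), Ednrb (-0.61), Cldn18 (-0.40), Lrrn4 (-0.92) and Msln (-1.02), with Ednrb at -0.000209, Ndrg1 at 0.0992 and Emcn at 0.26 against the AUS vehicle alone. Of the 36 named genes called, 12 passed against each vehicle group on its own: Ntrk2, Cdk19, Igfbp3, Nrxn1, Septin3, Col8a1, Aplnr, Car4, Sftpa1, Slc34a2, Etv5 and Serpina1b. A further 14 lists were called by camera and lost with an estimated correlation at adjusted p = 0.415 to 0.556 (limma; as for the model). Higher were the endothelial identity genes (0.22, 0.000276, 5 rose and 1 fell, 3 rose over all genes), vascular smooth muscle contractile genes (0.27, 0.000276, 6 rose, 2 over all genes), extracellular matrix genes (0.15, 0.000912, 9 rose and 2 fell, 5 rose and 1 fell over all genes) and hypoxia-inducible factor targets (0.20, 0.00203, 2 rose by either count). Glucocorticoid-responsive genes (0.30, 0.00551, 1 rose by either count), platelet and megakaryocyte markers (0.28, 0.0281) and C57BL/6 substrain genes (0.13, 0.0281, 2 rose, 1 over all genes) lay higher too. Lower were the mesothelial markers (-0.66, 1.33e-05, 7 fell, 2 over all genes), neutrophil markers (-0.84, 0.00203, 3 fell), alveolar type 1 markers (-0.26, 0.00365, 2 fell, 1 over all genes) and sterol and lipid synthesis genes (-0.10, 0.00444, 1 fell). Club cell markers (-0.40, 0.00577, 2 fell), unfolded protein response genes (-0.17, 0.0281) and alveolar macrophage markers (-0.18, 0.0384, 2 fell, 1 over all genes) lay lower too. In every fit with 1 library left out 13 of the 36 named genes called and 10 of 17 lists called by camera passed. Camera calls were lost (medians given) without ACE2 WT replicates 1 (unfolded protein -0.13, platelet 0.26, C57BL/6 substrain 0.13), 2 (sterol -0.05, alveolar macrophage -0.13, platelet 0.14) and 3 (glucocorticoid 0.19). The sign of the matrix list turned against the AUS vehicle alone (-0.13) and that of the unfolded protein response against the AR vehicle alone (0.20).

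ACE2-treated males labelled Mas KO were set against the same 6 vehicle libraries, where title set and genotype are confounded with treatment. The chemokine Cxcl12 rose to 1450 ± 100.5 against 541 ± 196 CPM (n = 3 against 6, log2 change 1.498 ± 0.12 SE, limma adjusted p = 3.26e-09), the angiogenic peptide gene Apln to 109 ± 4.31 against 36.4 ± 10.9 CPM (limma adjusted p = 7.44e-06) and Edn1, the endothelin precursor, to 162 ± 17.4 against 83.9 ± 20.8 CPM (log2 change 0.69 against the AUS vehicle alone, limma adjusted p = 0.0961). The Notch ligand Dll4 fell to 15.6 ± 3.77 against 61.4 ± 23.3 CPM (limma adjusted p = 0.000526). Oxygen-responsive Bnip3 rose to 122 ± 4.95 against 58.7 ± 11.3 CPM and the contractile Acta2 to 427 ± 45.9 against 281 ± 70.4 CPM. Neither passed against the AUS vehicle alone (log2 0.86 and 0.40). Targets of the aryl hydrocarbon receptor, Cyp1b1 (1518 ± 727 against 44.6 ± 35 CPM) and its repressor Ahrr (24.3 ± 9.26 against 1.77 ± 1.88 CPM), rose with wide spread.

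Here 1324 genes passed (2280 with array weights), 692 higher and 632 lower, and 343 passed in the same direction against each vehicle group on its own. Without replicates 2 and 3 of the libraries labelled Mas KO the counts were 691 and 556. Large changes by log2 were Nqo1 (2.79), Serpina1b (2.69) and Camk2b (2.56) upward and Cep85 (-2.34), Ifi208 (-2.29), Ankrd63 (-1.92) and Hmga1 (-1.79) downward, and Mas1 was called higher (1.39 ± 0.42 against 0.208 ± 0.151 CPM). Of 12 alveolar type 2 markers, 8 fell and 10 adjusted over the list alone (Slc34a2 (-0.68), Sftpa1 (-0.78), Lamp3 (-0.61) and Sftpd (-0.70), limma camera 3.15e-07 and 0.359 with an estimated correlation). Of 25 hypoxia-inducible factor targets, 11 rose and 1 fell, and 14 rose and 2 fell adjusted over the list alone (Aldoa (0.63), Ldha (0.61) and Ddit4 (0.94), limma 3.69e-06 and 0.266). Of 41 cell cycle genes 7 rose, and 23 adjusted over the list alone (Pbk (1.59), Ube2c (1.05), Ccna2 (1.06) and Mcm3 (0.38), limma 2.84e-08 and 0.628). Of 17 circadian clock genes 7 fell, and 8 adjusted over the list alone (Hlf (-1.26), Per3 (-1.07), Tef (-0.83) and Per2 (-1.20), limma 0.00164 and 0.348). Endothelial genes rose in 7 of 20, and 8 adjusted over the list alone (Emcn (1.12), Cdh5 (0.80), Esam (0.61) and Tie1 (0.67), limma 0.00069 and 0.601). Genes of the unfolded protein response fell in 6 of 19 with 1 rise, and in 13 with 1 rise adjusted over the list alone (Dnajc3 (-0.40), Hspa5 (-0.58), Xbp1 (-0.37) and Pdia4 (-0.43), limma 0.00069 and 0.601), but against the AR vehicle alone the median of the list was 0.0333.

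Further called members in the libraries labelled Mas KO by log2 change rose in contractile genes and pericyte genes (Cald1 (0.43), Myl9 (0.69), Tagln (0.56), Higd1b (0.77), Rgs5 (0.83), Ndufa4l2 (0.56) and Notch3 (0.42)), with Rgs5 at -0.23 and the matrix gene Eln at 0.13 against the AUS vehicle alone. They went both ways in matrix genes (Col8a1 (1.05), Eln (1.06), Mfap4 (0.82) and Col14a1 (-0.62)), endothelial subtypes (Glp1r (-1.04), Aplnr (-0.89), Gja4 (1.16) and Hey1 (-0.72)) and receptors or signalling genes (Adrb2 (0.61), Htr2a (1.21), Kcnk3 (-0.46), Bmp2 (1.05), Smad9 (-0.62), Tgfbr3 (-0.35) and Tgfb2 (0.33)). Peptidase genes of the angiotensin system changed, Anpep (-0.84) down and Prcp (0.97) up. Of 20 antioxidant genes 4 rose, 5 adjusted over the list alone, without a camera call (adjusted p = 0.153), Srxn1 (1.06), Txnrd1 (0.51) and Gstm1 (0.48) among them. Falls included sterol and lipid genes (Acly (-0.31), Lss (-0.48), Acaca (-0.31) and Idi1 (-0.41), the last -0.13 against the AR vehicle alone), interferon genes (Oas3 (-1.28) and Ifi44 (-0.66)), Hsp90aa1 (-0.81), epithelial genes (Rtkn2 (-0.56), Emp2 (-0.33), Vegfa (-0.32), Aldh1a7 (-0.56) and Sec14l3 (-0.67), with Igfbp2 up by 0.48 but 3.96e-05 against the AUS vehicle alone), monocyte genes (Ccr2 (-1.62), Ms4a6c (-1.19) and Fcgr1 (-0.81)) and Adrb3 (-0.92) and Msln (-0.89). The B cell kinase gene Blk rose (0.87). Of the 85 named genes called, 35 passed against each vehicle group alone, none of them contractile or pericyte genes. Camera called 13 more lists that were lost with an estimated correlation at adjusted p = 0.601 to 0.696 (limma; as for the model). Higher were the liver genes (1.36, 0.00219, 3 rose, 1 over all genes) and B cell markers (0.49, 0.00368, 2 rose, 1 over all genes). Lower were the neutrophil markers (-1.07, 0.00117, 5 fell), adipocyte markers (-1.10, 0.00164, 3 fell, 1 over all genes), cardiac muscle genes (-0.83, 0.0101) and sterol and lipid synthesis genes (-0.17, 0.0141, 1 rose and 4 fell, 4 fell over all genes). Club cell markers (-0.50, 0.0141, 2 fell, 1 over all genes), mesothelial markers (-0.46, 0.0209, 2 fell, 1 over all genes), alveolar type 1 markers (-0.18, 0.0218, 1 rose and 5 fell, 1 rose and 4 fell over all genes) and monocyte and interstitial macrophage markers (-0.25, 0.0269, 3 fell by either count) lay lower too. Heat shock genes (-0.45, 0.0294, 5 fell, 1 over all genes), interferon-stimulated genes (-0.22, 0.042, 2 fell by either count) and ciliated cell markers (-0.23, 0.0458, 1 fell by either count) lay lower too. Camera calls were lost (medians given) without Mas KO label replicates 1 (interferon -0.13), 2 (heat shock -0.42, alveolar type 1 -0.09, club cell -0.47, ciliated cell -0.13, monocyte -0.25, cardiac muscle -0.55, liver 0.07) and 3 (interferon -0.12, club cell -0.26, ciliated cell -0.12, monocyte -0.15, mesothelial -0.34). In every fit with 1 library left out 39 of the 85 named genes called and 10 of 19 lists called by camera passed.

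The vehicle males of the AUS and AR sets differ in title start and column name (SuHx and SuHxNew). Their comparison measures how far such sets stand apart. Chaperones of the endoplasmic reticulum were higher in the AUS set: Hspa5 reached 1050 ± 82 against 446 ± 30.9 CPM (n = 3 each, log2 change 1.23 ± 0.16 SE, limma adjusted p = 5.05e-05) and Manf 141 ± 19.7 against 55.7 ± 0 CPM. The matrix protease Mmp2 (369.9 ± 95.9 against 128 ± 8.88 CPM, limma adjusted p = 2.29e-06), the calcification inhibitor Mgp (2018 ± 307 against 765 ± 116 CPM) and the pericyte gene Rgs5 (45.3 ± 3.14 against 9.63 ± 0.381 CPM) were higher too. The endothelin receptor Ednrb was lower (45.7 ± 7.98 against 106 ± 4.31 CPM, limma adjusted p = 9.29e-05), as were the growth factor receptor Kdr (316 ± 21.9 against 559 ± 124 CPM) and the B lineage factor Pax5 (5.01 ± 1.11 against 20.4 ± 7.89 CPM).

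Between these vehicle groups 1991 genes passed (576 with the libraries of the comparison alone), 848 higher and 1143 lower in the AUS set, a split that TMM scaling turned to 1115 higher and 893 lower. The counts were 701 and 1261 without AR vehicle replicates 1 and 3, and 1199 and 739 without AUS vehicle male replicates 2 and 3. The leading changes by log2 were Ptx3 (2.48), Ccl21b (2.04), Slc26a10 (1.99) and Ccl21a (1.89) upward, the chemokine copies being uncertain, and Ankrd63 (-2.22), Hipk2 (-2.12), Kcna3 (-1.84) and Hydin (-1.84) downward. Of 39 extracellular matrix genes 22 rose, and 26 adjusted over the list alone (Mmp2 (1.49), Mfap5 (1.40), Bgn (0.90) and Fbln1 (0.89), limma camera 2.41e-16 and 0.0888 with an estimated correlation). Of 19 genes of the unfolded protein response 13 rose, and 17 with 1 fall adjusted over the list alone (Pdia4 (0.86) and Pdia6 (0.93), limma 3.92e-13 and 0.0591). Of 10 lymphatic endothelial markers 7 rose by either count, also adjusted over the list alone (Prox1 (1.19), Mmrn1 (0.95) and Thy1 (0.73)), and the call held (limma 8.58e-06 and 0.0137). Of 12 B cell markers 5 fell, and 7 adjusted over the list alone (Cd22 (-1.18), Bank1 (-1.22) and Cd19 (-1.44), limma 0.000111 and 0.489).

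More members differed between the vehicle sets. Fold change fell with transcript length (r = -0.385), and 918 of 1991 calls held without that trend. Surfactant and secretory genes (Cxcl15 (0.87), Sftpc (0.63), Muc1 (0.53) and Sftpb (0.40)), heat shock genes (Hspe1 (0.88), Hspd1 (0.59), Hsp90aa1 (0.83) and Hspb1 (1.26)), sterol genes (Cyp51 (0.52), Fdft1 (0.62), Msmo1 (0.55) and Idi1 (0.56)), respiratory chain genes (Cox6c (0.53), Atp5pb (0.46), Ndufb5 (0.39) and Cox4i1 (0.46)) and oxygen-responsive genes (Ndrg1 (0.82), Eno1 (0.66), P4ha1 (0.69) and Ldha (0.50)) were higher in the AUS set. Capillary genes (Glp1r (-0.90), Ptprb (-0.77) and Cd93 (-0.47)), ciliated cell genes (Sec14l3 (-0.80), Ccdc39 (-1.11), Dnah9 (-1.21) and Dnah5 (-1.08)), T cell genes (Ccr7 (-1.16), Bcl11b (-0.69), Cd8b1 (-0.92) and Tcf7 (-0.45)) and the killer cell genes Prf1 (-0.74) and Ncr1 (-0.76) were lower. Single members went both ways in vascular and signalling genes (Emcn (0.85), Sox18 (0.66), Cxcl12 (0.86), Gja4 (0.72), Fbln5 (0.46), Nos2 (1.19), Ece1 (-0.47), Bmp6 (-0.83), Id2 (0.62), Smad1 (0.42) and Bmpr2 (-0.50)), and Lcn2 (1.68), Sgk1 (0.73), Nr4a3 (-1.29), Ccne1 (0.64), Bst2 (0.59), Ifit1 (0.67), C1qc (0.52), Tcf21 (0.66), Dpep1 (0.40), Mfap4 (0.70), Plin2 (0.50), Cpt2 (0.55), Ppara (-1.01), Msln (0.99) and Upk1b (0.52) changed as well. So did Acat2 (0.45), Agpat4 (0.36) and Tcp1 (0.36), which lie near Mas1. A further 17 lists were called by camera but lost with an estimated correlation at adjusted p = 0.0591 to 0.646 (limma; as for the model). Higher were the oxidative phosphorylation genes (0.26, 1.42e-06, 9 rose, 7 over all genes), cell cycle genes (0.39, 0.000111, none, 1 rose over all genes), alveolar type 2 markers (0.42, 0.000258, 8 rose, 6 over all genes) and mesothelial markers (0.56, 0.000561, 4 rose, 2 over all genes). Heat shock genes (0.70, 0.00308, 5 rose by either count), monocyte and interstitial macrophage markers (0.50, 0.00338, none, 1 rose over all genes), sterol and lipid synthesis genes (0.16, 0.00905, 6 rose, 5 over all genes) and cardiac muscle genes (1.17, 0.00905) lay higher too. Glucocorticoid-responsive genes (0.51, 0.0136, 2 rose by either count), hypoxia-inducible factor targets (0.23, 0.0136, 8 rose and 2 fell, 8 rose and 1 fell over all genes), interferon-stimulated genes (0.23, 0.0431, 1 rose, 2 over all genes) and arterial and venous endothelial genes (0.20, 0.0431, 4 rose and 3 fell, 4 rose and 1 fell over all genes) lay higher too. Lower were the immediate early genes (-0.69, 0.00308, none, 1 fell over all genes), natural killer cell markers (-0.58, 0.00338, 2 fell by either count) and capillary endothelial subtype genes (-0.43, 0.00412, 7 fell, 4 over all genes). T cell markers (-0.45, 0.00458, 4 fell by either count) and ciliated cell markers (-0.33, 0.0171, 5 fell by either count) lay lower too. In every fit with 1 library left out 40 of the 89 named genes called and 12 of 21 lists called by camera passed. Camera calls were lost (medians given) without AR vehicle replicates 1 (arterial 0.17, interferon 0.11, ciliated cell -0.20), 2 (arterial 0.17, interferon 0.18, ciliated cell -0.13, T cell -0.30, killer cell -0.37) and 3 (sterol 0.07, cardiac muscle -0.24). Others were lost without AUS vehicle male replicates 1 (arterial 0.23, glucocorticoid 0.45), 2 (arterial 0.17, interferon 0.16, glucocorticoid 0.45) and 3 (immediate early -0.35). Of lists still called, the medians were 0.15 (oxidative phosphorylation), 1.00 (mesothelial), -1.14 (B cell) and -0.55 (ciliated cell) without AR vehicle replicate 3, 0.37 (mesothelial) without replicate 1 and 0.0832 (sterol) without AUS vehicle male replicate 2.

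The other similarities of fold changes across genes likewise missed the threshold by exact permutation of 400 labelings each. The difference of the libraries labelled Mas KO from WT, set against the model, had r = -0.113 and rho = -0.175 (exact permutation p = 0.57, adjusted p = 0.75), and of the 20 genes of the model 12 had the same sign there. AR234960 set against WT minus Mas KO had r = -0.142 and rho = -0.140 (exact permutation p = 0.41, adjusted p = 0.75). AR234960 set against Alt00/Lisi in males had r = -0.0692 and rho = -0.0878 (exact permutation p = 0.6, adjusted p = 0.75). Alt00/Lisi in males set against females had r = 0.0527 and rho = 0.0287 (exact permutation p = 0.77, adjusted p = 0.77).

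Cyp1a1, a target of the aryl hydrocarbon receptor chosen after its values were seen, ranged widely within groups. It lay at 26 to 34.3 CPM in normoxic males, 111 to 1663 in AR vehicle males and 955 to 2896 under AR234960. In the AUS set it lay at 3.73 to 294 CPM in vehicle males, 4.29 to 2195 in Alt00/Lisi males, 0.706 to 3566 in vehicle females and 2.46 to 2702 in Alt00/Lisi females. Under ACE2 it lay at 2896 to 5043 CPM in libraries labelled WT and 3566 to 5043 CPM in those labelled Mas KO.

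**Figure D4:**
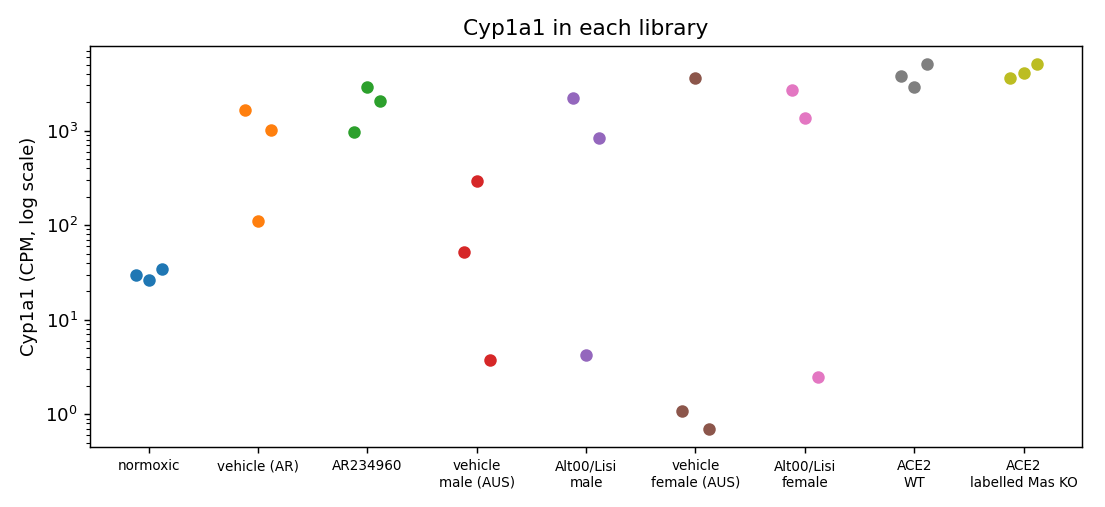
Cyp1a1 in CPM on a log axis in each of the 27 libraries, by group (points are libraries, 3 per group).

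Ace2, Ace, Agt and Agtr1a passed in none of the 12 comparisons by limma. Ace2 came nearest in AUS against AR vehicle males (10.7 ± 2.03 against 15.3 ± 1.2 CPM, limma adjusted p = 0.0557) and Agt, the angiotensin precursor, under ACE2 in wild-type males (4.25 ± 0.924 against 2.15 ± 1.18 CPM, n = 3 against 6, limma adjusted p = 0.0749). Ace, the converting enzyme, lay between 1127 and 1555 CPM and the receptor Agtr1a between 15.7 and 20.6 CPM as group means. The lists of renin-angiotensin and kinin genes, BMP and TGF-beta signalling, NRF2 antioxidant genes, fibroblast markers and neighbours of Mas1 were called by camera in none of the comparisons, with smallest adjusted p values of 0.329, 0.0958, 0.0960, 0.0625 and 0.150 (limma).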

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

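No test in this part was chosen after the result was seen. Of 46 gene lists, 13 differed between males and females in their change under Alt00/Lisi by limma camera on the interaction, and each lost the call with an estimated correlation. Lists are given as the median difference over members, female minus male. In parentheses are median changes in males and females and limma camera adjusted p (preset and estimated correlation).

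The change was higher in females than in males for the unfolded protein response at 0.35 (-0.33 and -0.0835, 8.86e-06 and 0.703), the monocyte and interstitial macrophage markers at 0.35 (-0.28 and 0.00321, 0.000242 and 0.703), the erythroid and haemoglobin genes at 1.38 (-0.34 and 1.03, 0.00334 and 0.912), the neutrophil markers at 0.44 (-0.59 and -0.23, 0.0196 and 0.964), the oxidative phosphorylation at 0.0987 (-0.033 and 0.0659, 0.0318 and 0.964), the arterial and venous endothelial genes at 0.26 (-0.13 and 0.0665, 0.0318 and 0.703) and the alveolar macrophage markers at 0.26 (-0.19 and -0.0254, 0.0328 and 0.912).

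It was lower in females than in males for the B cell markers at -0.61 (0.56 and -0.0813, 0.000242 and 0.912), the ciliated cell markers at -0.53 (0.23 and -0.26, 0.000376 and 0.912), the immediate early genes at -0.75 (0.47 and -0.15, 0.000388 and 0.912), the natural killer cell markers at -0.41 (0.26 and -0.17, 0.0196 and 0.912), the C57BL/6 substrain genes at -0.29 (0.16 and -0.13, 0.0318 and 0.703) and the T cell markers at -0.30 (0.28 and 0.00262, 0.0318 and 0.912).

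Adjusted over the list alone, 3 genes of the unfolded protein response and 2 monocyte markers passed the test of the difference. Of the 13 lists only the former was called with each library left out in turn. Without Alt00/Lisi female replicate 2, 10 of them lost the call, with medians such as 0.23 (erythroid), 0.0233 (neutrophil), -0.0218 (alveolar macrophage), -0.14 (killer cell) and -0.20 (T cell). Limma passed 0 genes for the difference, 1033 at an unadjusted p under 0.05. The 100 splits drawn of the 12 libraries decide nothing, since none can fall below the real 0, and the highest other gave 1055. What sets its sides apart was not tested. No explanation of these 13 differences was tested. They include the vehicle groups, where females differed from males with opposite sign in unfolded protein, monocyte, arterial, B, T and killer cell lists. Those lists do not isolate a response to treatment.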

How the results depend on the processing

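Of the results below, the counts against each vehicle group on its own, those outside chromosomes 4 and 17, the labelings that kept the vehicle shared and the calls in unchanged groups were tests chosen after the data were seen. No paired analysis was possible because replicate numbers follow the order of the records and tie no library to another. The alternatives meant for a count table (size factors in the count fit, the filter on counts and the count tests) were not run, since the table holds log2 CPM. The other alternatives were pseudocounts of 0.1 and 5 CPM, no filter, a mean of at least 5 CPM, quantile normalization, TMM scaling, array weights, the libraries of the comparison alone and, for similarities, genes with a mean of at least 10 CPM.

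Genes called with array weights numbered 234 for the model, 369 for AR234960, 1764 for AR234960 against normoxia, 11 for females against males, 101 for Mas KO label against WT, 996 for ACE2 WT and 2280 for ACE2 Mas KO label. With the libraries of the comparison alone limma called 13 for the model, 0 for AR234960, 693 for AR234960 against normoxia, 8 for Alt00/Lisi males and 576 for the vehicle sets, the count of 0 with 1477 at an unadjusted p under 0.05. Genes called against the AR vehicle alone numbered 1051 for ACE2 WT and 2508 for ACE2 Mas KO label. Those against the AUS vehicle alone numbered 200 and 720, and those against each on its own 59 and 343. Outside chromosomes 4 and 17, 7 genes passed between the libraries labelled Mas KO and WT. Of 180 list calls by camera, 9 held with an estimated correlation, and fry, which does not compare a list with other genes, called 41. The labelings that kept the vehicle shared gave an exact permutation p of 0.271 for AR234960 with the model. No gene passed for the sex difference of Alt00/Lisi under any alternative (limma; 1033 at an unadjusted p under 0.05 with all libraries), and pseudocount, filter and quantile settings kept the other counts within 1.5 times. The cause was not tested.

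Single genes and lists took the other sign under some settings (log2 change, or median for a list), and the cause was not tested. With array weights the value was 0.095 for Ace2 in Alt00/Lisi females. With a pseudocount of 0.1 CPM the value was -0.0772 for Mas1 in Alt00/Lisi females. With quantile normalization the value was 0.0664 for Mas1 in the model, -0.00546 for Mas1 in Alt00/Lisi females, -0.0848 for Ace in ACE2 Mas KO label and -0.17 for Ace in the vehicle sets. Against the AR vehicle alone the value was 0.0469 for Mas1 and 0.20 for unfolded protein response in ACE2 WT and 0.0333 for Hspa5 and 0.0333 for unfolded protein response in ACE2 Mas KO label. Against the AUS vehicle alone the value was 0.15 for Ace2 and -0.13 for extracellular matrix in ACE2 WT and 0.12 for Ace2 and -0.23 for Rgs5 in ACE2 Mas KO label. Calls against each vehicle group gave Mas1 and Hspa5 the values against AR.

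Leaving out 1 library at a time, where the 2 left in a group are taken to vary like the other groups, gave these ranges of called genes (limma): 2 to 14 for the model, 5 to 91 for AR234960, 60 to 290 for AR234960 against normoxia, 0 to 10 for Alt00/Lisi over both sexes, 0 to 21 for Alt00/Lisi males, 0 to 25 for Alt00/Lisi females, 0 to 0 for the sex difference of Alt00/Lisi, 4 to 7 for females against males, 20 to 27 for Mas KO label against WT, 143 to 354 for ACE2 WT, 556 to 1389 for ACE2 Mas KO label and 701 to 2536 for the vehicle sets. The correlations ran from -0.222 to 0.038 for Mas KO label with model, -0.212 to -0.00321 for AR234960 with WT minus Mas KO, -0.102 to 0.00938 for AR234960 with Alt00/Lisi, -0.528 to -0.21 for AR234960 with model and -0.0809 to 0.146 for Alt00/Lisi males with females (also -0.0364 and -0.0009). Genes and lists whose sign depended on 1 library (for heat shock genes the direction in camera, not the median) ran, in log2 change or median, with further values past 0 in parentheses, from -0.15 to 0.0763 (also 0.03) for Ace2 and -0.61 to 0.11 for immediate early genes in Mas KO label against WT, -0.0666 to 0.0833 (also -0.0333 and -0.0167) for Ace in ACE2 Mas KO label, -0.11 to 0.0485 for Mas1 and -0.20 to 0.0288 for Ace2 in ACE2 WT, -0.0869 to 0.0545 (also -0.0361) for Mas1, -0.13 to 2.21 for erythroid and haemoglobin genes and -0.25 to 0.0313 for Ace2 in Alt00/Lisi females, -0.0319 to 0.13 (also -0.00851, -0.00821, -0.00857 and -0.000566) for Agtr1a and -0.19 to 0.061 (also 0.0447) for Agt in Alt00/Lisi over both sexes, -0.64 to -0.16 for heat shock genes and -0.17 to 0.0319 (also 0.0152) for Agtr1a in Alt00/Lisi males, -0.22 to 0.0835 for Agt and -0.13 to 0.0198 (also 0.00428) for Mas1 in AR234960, -0.0934 to 0.0573 (also 0.0359) for Mas1, -0.20 to 0.0409 for oxidative phosphorylation, -1.28 to 0.85 for cardiac muscle genes and -0.67 to 0.21 for skeletal muscle genes in the model, -0.27 to 0.0645 (also 0.0173 and 0.0641) for Agtr1a, -0.13 to 0.0167 for Ace and -0.000974 to 0.29 for Ace2 in females against males and -0.0666 to 0.13 (also -0.05) for Ace and -0.24 to 1.94 for cardiac muscle genes in the vehicle sets. The median but not the camera direction passed 0 for hypoxia-inducible factor targets in AR234960 against normoxia (-0.0166 without AR234960 replicate 1) and alveolar macrophage markers in the sex difference of Alt00/Lisi (-0.0218 without Alt00/Lisi female replicate 2).

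Over all alternatives, gene results outside the counts stayed on their side of the threshold and in their direction 5145 times, lost the call 839 times, gained it 14 times and took the other sign 46 times, and list results kept both 2486 times, lost the call 331 times and took the other sign 10 times. Depth limits genes near 3 reads, such as Mas1 outside the libraries labelled Mas KO.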

Other observations

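Tests chosen after the result was seen were the counts on chromosomes 17 and 4, the exchange of labels, the correlation of receptor targets and the comparison of Cyp1b1 between ACE2 and vehicle libraries.

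Of the 29 genes called between the libraries labelled Mas KO and WT, 11 lie on chromosome 17, where 10000 random draws held 1.44 on average (95th percentile 4, 0 draws as many), and 8 on chromosome 4, where draws held 1.80 (95th percentile of the highest chromosome 6, as many on any chromosome in 55 draws). An exchange of the genotype labels is argued against by the 19 genes on these chromosomes: the libraries labelled WT lay outside the 21 other libraries at 0 of them and those labelled Mas KO at 18. Passenger DNA that travelled with the deletion may account for the 11 genes on chromosome 17, and a second segment for the 8 on chromosome 4, although strain variants were not measured. Loss of Mas itself stays open as a biological cause for any of these genes and for the 10 called elsewhere, since passengers and deletion go together in this design.

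Between the vehicle males of the AUS and AR sets, 1991 genes were called (576 with these libraries alone) although both carry the same treatment label. Removing each library's trend on transcript length left 1183 called genes (680 higher, 503 lower, 918 shared with the uncorrected calls) while the correlation of fold change with length went from r = -0.385 to 0.0273 across genes, so length alone is argued against, and removing the trend on GC content left 2611 (1933 shared). Depth is argued against, since 22.2% of genes in the highest quartile of mean level were called and 6.91% in the lowest. Differences in library preparation, date or animals between the sets remain open and cannot be told apart. The column names (SuHxNew for AR, SuHx for AUS) mark separate sets without a date or batch. No biological explanation was tested.

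Cyp1a1 and other targets of the aryl hydrocarbon receptor varied within groups. Shared activation of the receptor may underlie this: over 24 libraries outside normoxia, with group means removed, Cyp1a1 and the mean of 5 other targets (Cyp1a2, Tiparp, Aldh3a1, Ugt1a6a and Nfe2l2, singly at r = 0.748, 0.332, 0.130, 0.449 and 0.568) had Pearson r = 0.640 and Spearman rho = 0.577 (permutation p = 0.0386 and 0.0316, both 0.0386 adjusted over 2 tests). Without the 2 farthest libraries r was 0.476 (permutation p = 0.113) and rho 0.455 (p = 0.0842), so the call rests on those libraries. Liver as the source of Cyp1a1 is argued against. Alb exceeded it in 0 of 14 libraries with over 1000 CPM of it and reached 59.7 CPM at most. For the liver genes under ACE2, traces of liver stay open. ACE2 treatment cannot be told apart from the title set: Cyp1b1 lay above all 9 vehicle libraries (highest 1097.5 CPM) in 4 of 6 ACE2 libraries (549 to 2353 CPM), and 0 vehicle libraries share their title start.

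Splits of the same libraries into groups of the same sizes were refitted with limma. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 20 and 0 for the model, 30 and 2 for AR234960, 286 and 0 for AR234960 against normoxia, 29 and 12 for the libraries labelled Mas KO against WT and 1991 and 480 for the vehicle sets, with 1 of 10 splits as high in each. They were 7 and 10 for females against males (2 of 10 splits as high), 0 and 0 for Alt00/Lisi in males (10 of 10, limma, 1143 at an unadjusted p under 0.05) and 0 and 21 in females (10 of 10, 1088). Over both sexes the 100 splits drawn decide nothing, since none can lie below the real 0 (limma, 1140 at an unadjusted p under 0.05). The highest gave 1165 genes, and what sets the sides of that split apart was not tested.

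For ACE2 in wild-type males, 5 of 84 splits of the 9 libraries gave as many genes as the real 188 in this fit, so chance cannot be excluded. For ACE2 with the Mas KO label 3 of 84 gave as many as the real 918, a share under 0.05, which is 1 of 12 such tests. The splits exchange libraries between title sets that differ at 1991 genes, so neither share tells treatment from set. In both the highest count, 1801 and 2536, came from the split of the 3 AR vehicle libraries from the rest, which follows the title sets.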
